A study of Homo sapiens with 12 samples.

How the data were processed

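Polyadenylated RNA of 4 HMLE-derived lines was measured by RNA sequencing, with 3 samples per line and 12 in all. Per the labels' protocols, RNA was purified with an RNeasy kit, ERCC spike-in RNA was added, and libraries were made with a NEBNext Ultra kit. Per the submitters' processing notes, Trimmomatic 0.39, STAR 2.7.5c, Picard and SAMtools were used, and the builds hg38 and hg19 are both named without their roles. The counting tool, the annotation release and the use of strand are not given in the sources used here.

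The deposited values were expected counts per gene, estimated counts that need not be whole, in 61533 gene entries per sample. They were rounded to whole numbers, which changed 6.75% of the values by at most 0.5. The design, fixed before the data were examined, had assumed raw counts; the same test was kept on the rounded expected counts. No column held values without a sample. Of the gene identifiers, 61369 matched a symbol and 58356 are in GENCODE 29, from which GRCh38 coordinates, transcript lengths and GC content were taken. The 46 entries for the second copy of pseudoautosomal genes were kept as given. The files held 0 ERCC entries, so no spike-in scaling could be made.

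Total counts per library after rounding were 13322838, 11359326 and 12094351 for control, 11584649, 11322851 and 10399480 for CT83, 14159740, 10508868 and 11721709 for HORMAD1, and 11507982, 11592870 and 9898845 for the double line (replicates 1 to 3). A floor of 3 counts per library was used where a gene had no counts. Intervals and floors cover counting error only. The median SE of a log2 fold change was 0.13 between lines and 0.18 for the interaction.

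Samples were grouped by the labels. In R 4.3.3, genes were filtered with filterByExpr of edgeR 4.0.16 at a minimum count of 10, which left 15616 genes, and scaled by TMM. A quasi-likelihood model with robust dispersions was fitted to all 12 samples with 1 mean per line and 8 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each of 6 comparisons: the CT83, HORMAD1 and double lines against control, the double line against each single line, and the interaction on the log2 scale. Counts of called genes from each tool hold the transgenes where these passed, unless they are named apart. A prior count of 2 was used for log2 CPM of each library. CPM values are normalised and given as mean ± SD of 3 samples.

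Gene lists were fixed before the data were examined, 29 in number, with HORMAD1 and CT83 left out of each. Lists with at least 5 members tested (25 lists) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. For lists, a mean log2 CPM over members, relative to the mean of the 12 libraries, was compared between lines with an exact two-sided permutation test, which cannot go below 0.1 with 3 against 3. Correlations over the 12 libraries were tested by shuffling all 12 without keeping to lines, so their p-values may be too small.

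Genes were named by a rule fixed before the data were examined. It took the transgenes, and up to 6 called genes with the largest and 6 with the smallest log2 fold change per comparison that had a symbol, a mean log2 CPM of at least 2 and no overlap between the groups. It also took up to 4 members with the smallest adjusted p of each called list, and 16 fixed genes in the comparisons against control. Members called over their list alone and genes of single libraries were named in addition, after their values were seen. Overlapping and antisense genes were treated as uncertain. Values of some single genes are not reported here.

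The model and the list test were checked on simulated counts for the double line against control with 15435 genes. There, 67, 67 and 66 genes with a log2 mean CPM over 2 were changed 1.5-fold, 2-fold and 4-fold at once, and a list was shifted. Of these genes, 41.8%, 88.1% and 97% were recovered, and 7 unchanged genes were called. The shifted list had a camera adjusted p of 1.38e-08 and 0 other lists were called. The adjustment is stricter where few genes change, so these shares do not give the power of comparisons with few calls. With no change simulated for the CT83 line against control, 0 genes and 0 lists were called by the same tests. Simulated genes were drawn independently of each other and without a trend on transcript length. These counts and recovered shares therefore do not cover correlated members or that trend. Other splits of the real libraries called a median of 4 to 6 lists. No replicate pair differed by less than sampling noise, with chi-square per degree of freedom of 2.54 to 26.41.

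The processing choices varied were DESeq2 size factors, upper-quartile scaling and library size alone in place of TMM; no low-count filter and a stricter one (CPM of at least 1 in 3 samples); DESeq2 1.42.0 and limma-voom; a fit of only the groups compared; the replicate number as a block; an adjusted p under 0.01; a log2 fold change of at least 1; an estimated correlation; and leaving out each library. After the data were seen, 2 were added. The first was a correction for a smooth trend on transcript length and GC content, fitted per library with mgcv 1.9.3 (basis of 5 per axis). It used all genes of known length and GC content. The second was leaving out the 3 libraries that rose most steeply with transcript length. They were chosen from these same data, and the fit without them had 5 residual degrees of freedom. Leaving out libraries that stand apart from others of their line can by itself narrow the spread and raise the number of calls. The slopes on transcript length came from a straight-line fit per library on log length and GC content together, over genes with mean log2 CPM over 3. Length and GC content were known for 15341 of the 15616 genes (98.2%). Tables and plots were made with Python 3.11.15.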

Results

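Messenger RNA of 4 cell lines derived from HMLE cells was sequenced. HMLE is a line of human mammary epithelial cells immortalised with telomerase and SV40 antigens. Per the labels, the 4 lines carried a control construct, CT83, HORMAD1, or both HORMAD1 and CT83 (the double line), and were selected with puromycin. HORMAD1 encodes a protein of the meiotic chromosome axis, and CT83 (also KK-LC-1) is a cancer/testis gene of the X chromosome. The design asked what each gene did in these cells and whether they cooperated. Each line had 3 replicate libraries, 12 in all, with 9898845 to 14159740 expected counts per library, after rounding, over 61533 gene entries. The labels do not say whether the replicates were separate cultures, so p-values measured only the spread between these libraries, which may be technical. With 1 line per construct, an effect of a transgene could not be separated from a difference between lines.

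Both transgenes followed the labels in all 12 libraries. HORMAD1 (ENSG00000143452.16, protein coding, chromosome 1, 150698060 to 150720888, minus strand of GRCh38) had 0 counts in every control and CT83 library. It reached 290 ± 75.5 CPM in the HORMAD1 line and 314 ± 31.8 CPM in the double line (SD, n = 3 each), at least 1170-fold and 1270-fold higher than the control floor of 3 counts per library. CT83 (ENSG00000204019.5, protein coding, chromosome X, 116461682 to 116463003, minus strand) had 0 counts in every control and HORMAD1 library. Its level was 523.4 ± 175 CPM in the CT83 line and 101.9 ± 15.6 CPM in the double line (SD, n = 3 each), at least 2110-fold and 412-fold higher than the control floor. The floors cover counting error only. The double line thus held 19.5% of the CT83 transcript of the CT83 line, 86.7 to 117.8 CPM against 400.2 to 723.7 CPM, without overlap of the libraries (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). HORMAD1 transcript did not differ between its 2 lines beyond the spread (exact two-sided permutation p = 0.8).

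For the lower CT83 level of the double line, the log2 fold change against the CT83 line was -2.36. Its Benjamini-Hochberg adjusted p was 0.585 in edgeR's quasi-likelihood test, 6.12e-11 in DESeq2 and 3.1e-05 in limma-voom. Against control, CT83 passed edgeR's test in the CT83 line (adjusted p = 0.0267) and in the double line (adjusted p = 0.0351). Both calls were lost without control replicate 2, CT83 replicate 2, HORMAD1 replicate 1 or any double replicate, and the call in the double line also without control replicate 1 (edgeR adjusted p up to 0.315 and 0.257), although no control library held a CT83 count. Both CT83 calls were also lost without a low-count filter (edgeR adjusted p = 0.295 and 0.0885) and after the length and GC correction (0.0525 and 0.0596). With only the groups compared, the call in the CT83 line was lost (0.938). HORMAD1 passed in the HORMAD1 line (edgeR adjusted p = 0.00211) and in the double line (0.00196), and stayed called without any 1 of the 12 libraries. In the HORMAD1 line its call was lost without a low-count filter (0.0582) and with only the groups compared (0.113).

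**Figure D1:**
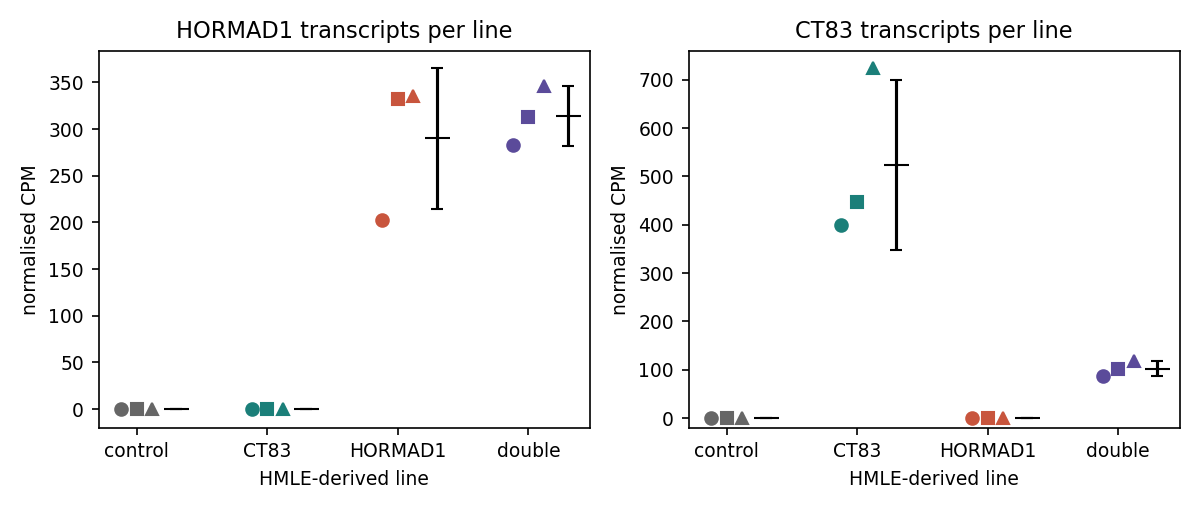
Normalised CPM of HORMAD1 (left) and CT83 (right) in the 12 libraries by HMLE-derived line; circles, squares and triangles are replicates 1, 2 and 3, and the bars are mean ± SD (n = 3). CT83 lay between 86.7 and 117.8 CPM in the double line and between 400.2 and 723.7 CPM in the CT83 line, and both genes were at 0 in the lines without their transgene.

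In the CT83 line against control, the differences called besides the transgene were lower levels of lists of related genes. None of these lists was called with an estimated correlation (camera adjusted p of 0.417 or more). Keratins of the luminal layer had lower values, with KRT8 at 1920 ± 57.9 against 2410 ± 180 CPM (log2 fold change -0.33, SE 0.11) and KRT18 at 971 ± 42.6 against 1170 ± 72.4 CPM (-0.27, SE 0.1). The surface glycoprotein CD24 was at 320 ± 38.5 against 434 ± 11.5 CPM (-0.44, SE 0.17; SD, n = 3 each). Among mesenchymal genes, the matrix protein SPARC had a log2 fold change of -0.16 (SE 0.07), the adhesion molecule CDH2 -0.5 (SE 0.26) and the collagen COL3A1 -2.42 (SE 1), the last resting on control replicate 3 with 6.57 CPM. The fibroblast markers DCN and LUM, near the floor of detection, were at 0.0843 to 1.06 CPM in the controls. In the 3 CT83 libraries DCN was at 0.343, 0 and 0.0956 CPM and LUM at 0 CPM. FAP, a more abundant fibroblast marker, was at 17.1, 17.4 and 17.6 CPM in the CT83 line against 19.4, 22 and 19.8 CPM in the controls (edgeR adjusted p = 0.984). MFAP5 was at 0.605 to 1.53 against 1.05 to 2.7 CPM. The basal markers KRT5, KRT14 and TP63 had log2 fold changes of -0.12, 0.07 and 0.06.

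By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 15616 genes, the CT83 transgene alone was called, and 0 other genes. An unadjusted p under 0.05 was reached by 428 genes, 2.7% of those tested, and DESeq2 and limma-voom also called 1 gene each. KRT8, KRT18, CD24, SPARC, CDH2 and COL3A1 all had an edgeR adjusted p of 0.984.

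By the camera test with preset correlation 0.01 and Benjamini-Hochberg adjustment, 7 of 25 lists were lower in the CT83 line. They were mesenchymal genes (median log2 fold change -0.22, 21 of 23 members below 0, adjusted p = 0.000467; adjusted p = 0.502 with an estimated correlation) and luminal genes (-0.12, 8 of 11, adjusted p = 0.00398; adjusted p = 0.417 with an estimated correlation). Interferon-stimulated genes (-0.1, 13 of 18) and hypoxia and glycolysis genes (-0.1, 15 of 20) each had a camera adjusted p of 0.00934, with adjusted p = 0.502 and adjusted p = 0.417 with an estimated correlation. The unfolded protein and integrated stress response list (-0.09, 16 of 19) had a camera adjusted p of 0.0123 (adjusted p = 0.668 with an estimated correlation) and the epithelial list (-0.06, 22 of 29) 0.015 (adjusted p = 0.668 with an estimated correlation). YAP/TAZ targets (-0.1, 13 of 21) had a camera adjusted p of 0.0364 (adjusted p = 0.708 with an estimated correlation). In these lists 0 members were called over all genes and 0 when adjusted over the list alone. TAGLN, an actin-binding protein of the basal list, which camera did not call, passed when adjusted over the list alone (log2 fold change -1.18, edgeR adjusted p = 0.0314) and not over all genes (0.984). The adjustment over a list alone was not corrected across the 25 lists.

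Each of these 7 list calls was lost without at least 1 library. Leaving out CT83 replicate 2 ended 6 of them (camera adjusted p = 0.0592 for the mesenchymal and stress lists, 0.0624 for the hypoxia and interferon lists, 0.0791 for the epithelial and 0.578 for the YAP/TAZ list). Leaving out CT83 replicate 1 ended the luminal, epithelial and YAP/TAZ calls (0.156, 0.466 and 0.921), and CT83 replicate 3 the interferon and stress calls (0.179 and 0.0645). Control replicate 2 carried the luminal, epithelial, YAP/TAZ and interferon calls (0.326, 0.326, 0.489 and 0.057 without it), control replicate 3 the stress call (0.0506) and HORMAD1 replicate 1 the YAP/TAZ call (0.0545). Without the 3 libraries that rose most steeply with transcript length (control replicate 2, CT83 replicate 3 and HORMAD1 replicate 1), left out together after the data were seen, edgeR called 40 genes higher and 79 lower, and the interferon call was lost (0.255). Without a low-count filter the luminal call was lost as well (0.0559).

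In the HORMAD1 line against control, genes of NF-kB and inflammatory signalling were higher as a group (camera adjusted p = 1.11e-06; adjusted p = 0.0795 with an estimated correlation). The cytokine IL1A stood at 187 ± 13.5 against 140 ± 6.68 CPM (log2 fold change 0.43, SE 0.1), and BIRC3, an inhibitor of apoptosis induced by NF-kB, at 145 ± 9.28 against 108 ± 14 CPM (0.43, SE 0.11; SD, n = 3 each). The chemokine CCL20 and the cytokine LIF had log2 fold changes of 0.79 (SE 0.32) and 0.69 (SE 0.33). The mesenchymal list was lower by camera (adjusted p = 1.93e-06; adjusted p = 0.392 with an estimated correlation), while its mean in HORMAD1 replicate 1, 0.29, lay within the controls' 0.13 to 0.43 (exact two-sided permutation p = 0.3). VIM, an intermediate filament, was at 238 ± 7.94 against 296 ± 14.8 CPM (-0.31, SE 0.14) and the transcription factor TWIST1 at -0.42 (SE 0.2). COL3A1 (-2.78, SE 1.02) again rested on the 6.57 CPM of control replicate 3. DCN (0.253 to 1.06 CPM in the controls) and LUM (0.0843 to 0.525 CPM) were at 0.27 and 0.337 CPM in HORMAD1 replicate 1 and at 0 in the other 2 HORMAD1 libraries. FAP was at 19.3 to 20.4 against 19.4 to 22 CPM and MFAP5 at 0.674 to 1.4 against 1.05 to 2.7 CPM. The Notch ligand JAG1 (-0.31, SE 0.09) and the Notch target NRARP (-0.52, SE 0.19) also had lower values, while CDH1, EPCAM and TP63 had log2 fold changes of 0.03, -0.03 and 0.01.

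HORMAD1 itself was the single gene called by edgeR, with 0 others. A total of 284 genes (1.8%) reached an unadjusted p under 0.05, limma-voom called 1 gene and DESeq2 2, all higher. The named genes of the lists and the fixed genes had an edgeR adjusted p of 1. When adjusted over the list alone, IL1A (edgeR adjusted p = 0.0161) and BIRC3 (0.0174) passed, 2 of 18 NF-kB members against 0 over all genes, and 0 members of the other called lists passed either way.

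Camera called 5 of 25 lists in this line. The NF-kB and inflammatory list was higher (median log2 fold change 0.25, 16 of 18 members above 0, Benjamini-Hochberg adjusted p = 1.11e-06; adjusted p = 0.0795 with an estimated correlation). Lower were the mesenchymal list (-0.24, 20 of 23 below 0, camera adjusted p = 1.93e-06; adjusted p = 0.392 with an estimated correlation) and the unfolded protein and integrated stress response list (-0.12, 18 of 19, 0.000167; adjusted p = 0.497 with an estimated correlation). The keratinocyte differentiation list (-0.12, 12 of 16, camera adjusted p = 0.0081; adjusted p = 0.392 with an estimated correlation) and the Notch list (-0.01, 7 of 12, 0.01; adjusted p = 0.392 with an estimated correlation) were lower too. As a mean over members, the NF-kB list stood at 0.25 ± 0.19 in the HORMAD1 line and 0.01 ± 0.08 in control (log2 CPM relative to the 12-library mean, SD, n = 3), with 2 of 3 HORMAD1 libraries above all controls (exact two-sided permutation p = 0.2).

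The NF-kB and mesenchymal calls held without any 1 of the 12 libraries, with camera adjusted p of at most 0.00422 and 0.016. The stress call was lost without HORMAD1 replicate 1 (0.787), the keratinocyte call without HORMAD1 replicate 1 (0.37), HORMAD1 replicate 2 (0.11) or control replicate 1 (0.0502), and the Notch call without HORMAD1 replicate 2 (0.135), HORMAD1 replicate 3 (0.148), control replicate 2 (0.142) or the low-count filter (0.113). When the 3 libraries with the steepest length trend were left out, edgeR called 6 genes higher and 0 lower, and the camera calls of the stress and keratinocyte lists were lost (0.484 and 0.358).

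The double line differed from control in 2 genes besides its transgenes, both lower. AIF1L, an actin-binding protein (chromosome 9, 131096476 to 131123152), was at 4.16 ± 0.878 against 10.2 ± 2.15 CPM (SD, n = 3 each), a log2 fold change of -1.29 (SE 0.2). CPVL, a carboxypeptidase-like protein (chromosome 7, 28995231 to 29195451), had a log2 fold change of -2.03 (SE 0.29); it lies below the expression minimum for named genes and was chosen after its values were seen. The epithelial junction list was lower by camera (adjusted p = 6.84e-07; adjusted p = 0.376 with an estimated correlation). E-cadherin (CDH1) was at 293 ± 17.6 against 377 ± 20.9 CPM (-0.36, SE 0.1) and the tight-junction protein CLDN4 at 89.2 ± 0.953 against 119 ± 4.93 CPM (-0.42, SE 0.12), each with an edgeR adjusted p of 0.712. The luminal keratins KRT8 (-0.33, SE 0.11) and KRT18 (-0.3, SE 0.1) and the luminal transcription factor GATA3 (-0.53, SE 0.19) had lower values. VIM, SNAI2 and ZEB1, genes of the mesenchymal state, had log2 fold changes of 0.11, 0.14 and 0.54 with SE 0.14, 0.13 and 0.46. The fibroblast marker FAP was at 22.5, 22.5 and 22.4 against 19.4, 22 and 19.8 CPM in control. Near the floor, DCN was at 0.532, 0.526 and 1.41 against 1.06, 0.35 and 0.253 CPM. LUM was at 0.444, 0.438 and 1.31 against 0.379, 0.525 and 0.0843 CPM, and MFAP5 at 0.355, 1.23 and 0.805 against 1.29, 1.05 and 2.7 CPM.

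In edgeR's quasi-likelihood test, AIF1L (Benjamini-Hochberg adjusted p = 0.045) and CPVL (0.0351) were called beside the transgenes, and 868 genes (5.6%) reached an unadjusted p under 0.05. DESeq2 called 2 genes higher and 3 lower, limma-voom 2 higher and 0 lower. In both tools the higher genes were the transgenes. CDH1 and CLDN4 each had an edgeR adjusted p of 0.0486 adjusted over the list alone, 2 of 29 members against 0 over all genes. TNFAIP3, a feedback inhibitor of NF-kB, passed adjusted over the list alone (-0.49, edgeR adjusted p = 0.0141), as did the protease inhibitor TIMP3 (-0.26, 0.0446), and neither over all genes (0.652 and 0.712).

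Camera called 5 of 25 lists in the double line against control. The epithelial list was lower (median log2 fold change -0.21, 25 of 29 members below 0, Benjamini-Hochberg adjusted p = 6.84e-07; adjusted p = 0.376 with an estimated correlation), as were the luminal list (-0.3, 8 of 11, 0.000249; adjusted p = 0.288 with an estimated correlation) and the YAP/TAZ list (-0.2, 18 of 21, 0.000959; adjusted p = 0.689 with an estimated correlation). Immediate early genes, which are induced within minutes of a stimulus, were lower (-0.28, 11 of 12, camera adjusted p = 0.00754; adjusted p = 0.58 with an estimated correlation), with KLF6 at -0.34 (SE 0.11). Ribosomal protein genes were higher (0.1, 42 of 46 above 0, camera adjusted p = 3.01e-05; adjusted p = 0.689 with an estimated correlation), with RPL5 at 0.33 (SE 0.12). Within lines, the ribosomal protein level of a library followed its trend on transcript length (Pearson r = -0.98 over 12 libraries, permutation p = 1e-05, the smallest these permutations can give; Spearman rho = -0.94, p = 4e-05; r = -0.97 without the 2 farthest libraries). This was 1 of 3 relations computed, with Benjamini-Hochberg adjusted p of 3e-05 and 0.00012. The permutations shuffled all 12 libraries without keeping to lines, so these p-values may be too small. The 3 libraries with the steepest rise along transcript length lay in the other 3 lines, 1 in each.

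The mean of the epithelial list was -0.12 ± 0.06 in the double line and 0.05 ± 0.05 in control, and all 3 double libraries lay below all 3 controls (SD, n = 3; exact two-sided permutation p = 0.1, the smallest possible). Of the calls, AIF1L was lost without 9 of the 12 libraries in turn (edgeR adjusted p up to 0.399), namely all but control replicate 3, CT83 replicate 3 and HORMAD1 replicate 1. CPVL was lost without any control replicate, CT83 replicate 2, HORMAD1 replicate 2 or double replicate 1 or 3 (up to 0.241). The replicate block (adjusted p = 0.231 and 0.108) and limma-voom (0.191 and 0.0774) also ended the calls of AIF1L and CPVL. AIF1L was lost after the length and GC correction (edgeR adjusted p = 0.0596) and with library size alone (0.0665) too. The YAP/TAZ call was lost without double replicate 1 (camera adjusted p = 0.106) and the immediate early call without double replicate 2 (0.0755). Without the 3 libraries with the steepest length trend, edgeR called 3 genes higher and 10 lower, and these held all 4 genes called with 12 libraries.

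**Figure D2:**
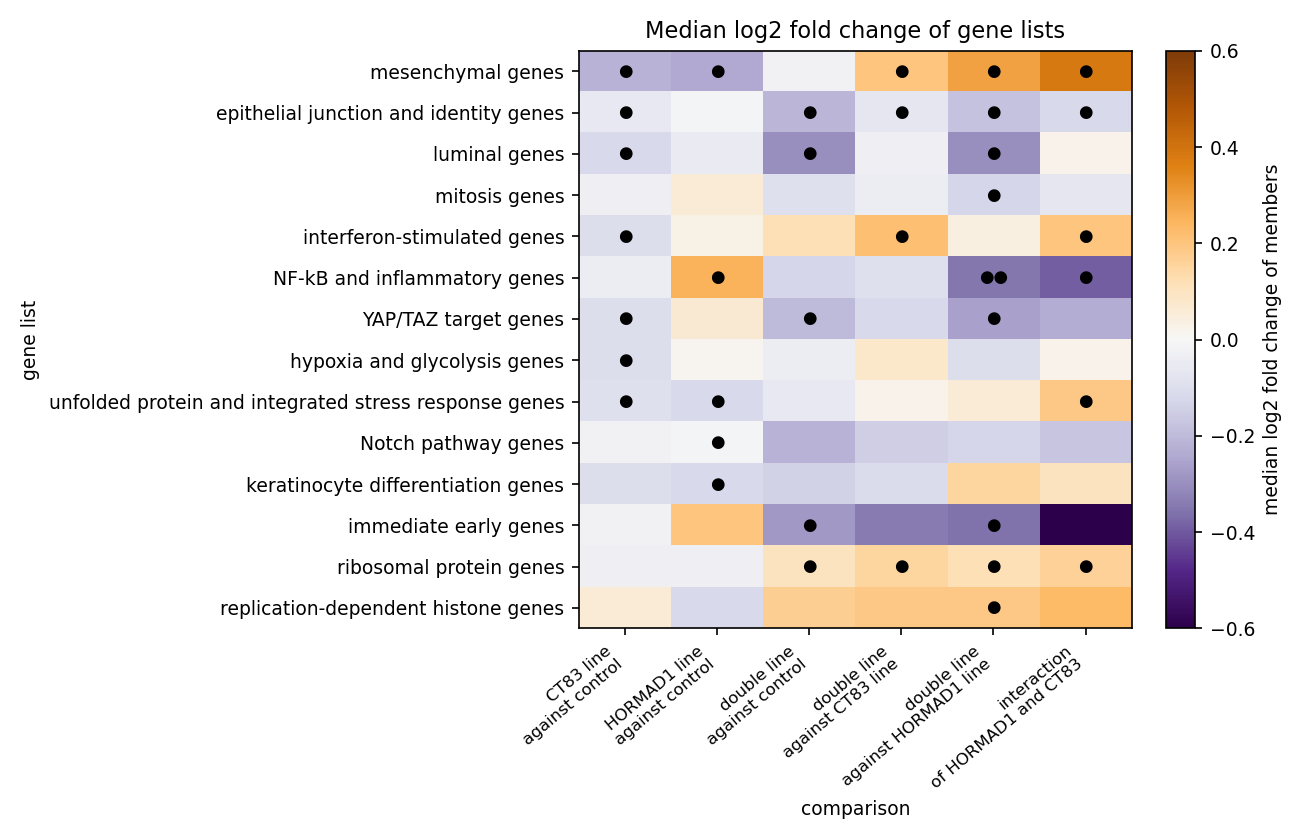
Median log2 fold change of the members (colour, purple lower and orange higher) of the 14 gene lists called in at least 1 of the 6 comparisons; 1 dot marks a camera adjusted p under 0.05 with the preset correlation and 2 dots a call that also held with an estimated correlation. The NF-kB and inflammatory list in the double line against the HORMAD1 line, at -0.35, is the cell with 2 dots.

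Against the CT83 line, the double line showed the HORMAD1 transgene, lower CT83 and small shifts in 4 lists, none of them called with an estimated correlation (camera adjusted p = 0.814 each). The transcriptional repressor SNAI2 was at 73.3 ± 4.12 against 56.8 ± 11.6 CPM (log2 fold change 0.37, SE 0.13; SD, n = 3 each), and the matrix glycoprotein TNC at 86.9 ± 11.4 against 124 ± 37.8 CPM (-0.51, SE 0.2). The matrix protein FBN1 (1.56, SE 0.65) was highest in double replicate 3, at 8.96 CPM. The interferon-stimulated genes IFI44 and ISG15 had log2 fold changes of 0.4 (SE 0.14) and 0.25 (SE 0.1). The desmosomal protein PKP3 was at 124 ± 11.8 against 158 ± 28.4 CPM (-0.36, SE 0.13), and the splicing factor ESRP2 at -0.29 (SE 0.12).

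EdgeR called HORMAD1 (Benjamini-Hochberg adjusted p = 0.00211) and 0 other genes, while 1257 genes (8%) reached an unadjusted p under 0.05. DESeq2 called 2 genes higher and 1 lower, and limma-voom 1 higher and 1 lower. In both tools the lower gene was CT83, and HORMAD1 was among those higher. The members named for this comparison had an edgeR adjusted p of 0.585, and 0 members of any list passed over all genes or adjusted over the list alone.

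Camera called 4 of 25 lists against the CT83 line, all with adjusted p = 0.814 with an estimated correlation. Ribosomal protein genes (median log2 fold change 0.15, 43 of 46 above 0, Benjamini-Hochberg adjusted p = 1.57e-07), interferon-stimulated genes (0.22, 15 of 18, 0.00827) and mesenchymal genes (0.2, 15 of 23, 0.0418) were higher by camera, and epithelial genes were lower (-0.07, 21 of 29 below 0, 0.0418). Of the fibroblast markers, FAP was at 22.5, 22.5 and 22.4 against 17.1, 17.4 and 17.6 CPM (edgeR adjusted p = 0.585). DCN was at 0.532, 0.526 and 1.41 against 0.343, 0 and 0.0956 CPM. LUM was at 0.444, 0.438 and 1.31 CPM against 0 in all 3. MFAP5 was at 0.355, 1.23 and 0.805 against 0.771, 0.605 and 1.53 CPM. The ribosomal protein level followed the length trend within lines in all 12 libraries (Pearson r = -0.98), which bears on each comparison of the double line. The ribosomal protein call was lost without CT83 replicate 3 (camera adjusted p = 0.0699), the interferon call without CT83 replicate 2 (0.0522) or double replicate 1 (0.0623), the mesenchymal call without CT83 replicate 1 (0.108), CT83 replicate 2 (0.392) or double replicate 3 (0.319), and the epithelial call without CT83 replicate 2 (0.0522), CT83 replicate 3 (0.314), double replicate 3 (0.293) or control replicate 3 (0.051). Without the 3 libraries with the steepest length trend, edgeR called 42 genes higher and 31 lower, and the ribosomal protein (camera adjusted p = 0.0587), interferon (0.0742) and epithelial (0.225) calls were lost. Upper-quartile normalisation ended the mesenchymal and epithelial calls (0.051 each), and a correction for transcript length and GC content the epithelial call (0.232).

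Against the HORMAD1 line, the double line had lower levels of NF-kB targets (camera adjusted p = 1.28e-08; adjusted p = 0.0402 with an estimated correlation) and of 6 single genes. The epithelial list was lower by camera (8.77e-08) but not with an estimated correlation (adjusted p = 0.215 with an estimated correlation). BIRC3 was at 92.8 ± 11.6 against 145 ± 9.28 CPM (log2 fold change -0.64, SE 0.12), TNFAIP3 at 34.2 ± 2.72 against 52.1 ± 1.96 CPM (-0.61, SE 0.12) and the prostaglandin synthase PTGS2 at 10.4 ± 0.772 against 19.5 ± 5.33 CPM (-0.9, SE 0.21; SD, n = 3 each). CLDN4 (-0.57, SE 0.12), the junction protein OCLN (-0.53, SE 0.14), CDH1 (-0.39, SE 0.1) and the epithelial transcription factor OVOL1 (-0.67, SE 0.17) had lower values. AIF1L fell to 4.16 ± 0.878 from 12 ± 1 CPM (-1.52, SE 0.2), C15orf48, a small mitochondrial protein, to 2.73 ± 0.629 from 9.43 ± 1.34 CPM (-1.77, SE 0.25), and B4GALT5, a galactosyltransferase, to 115 ± 2.36 from 155 ± 8.47 CPM (-0.43, SE 0.07). VIM was at 320 ± 44.4 against 238 ± 7.94 CPM (0.43, SE 0.14), and the stress kinase NUAK2 of the YAP/TAZ list at -1.15 (SE 0.26).

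By edgeR with Benjamini-Hochberg adjustment, the CT83 transgene was higher (adjusted p = 0.0217; up to 0.172 without CT83 replicate 2, any HORMAD1 replicate or any double replicate) and 6 genes were lower. These were AIF1L and C15orf48 (0.0172 each), B4GALT5 (0.0449), CPVL (-1.93, SE 0.3, 0.023), ENSG00000288528 (-0.77, SE 0.11, 0.0172) and ENSG00000259342 (-1.5, SE 0.22, 0.0217); the last 3 fell outside the naming rule and were chosen after their values were seen. C15orf48 (chromosome 15, 45430529 to 45448761, plus strand) and the antisense gene ENSG00000259342 (45430652 to 45441808, minus strand) overlap over 11157 bases. The strand setting of the counting is not given in the sources used here, so their counts are uncertain and may be 1 signal. CPVL likewise overlaps CHN2 on the other strand over 48883 bases. B4GALT5 lies on chromosome 20 (49632945 to 49713878), and ENSG00000288528 has no entry in GENCODE 29.

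An unadjusted p under 0.05 was reached by 1185 genes (7.6%), DESeq2 called 28 genes higher and 29 lower, and limma-voom called 1 higher and 2 lower. All 6 lower calls were lost without HORMAD1 replicate 2, HORMAD1 replicate 3 or any double replicate; the highest edgeR adjusted p was 0.15 for AIF1L, 0.172 for C15orf48 and for ENSG00000288528, 0.203 for ENSG00000259342, 0.156 for CPVL and 0.311 for B4GALT5. The B4GALT5 call was also lost without any control replicate, CT83 replicate 1 or CT83 replicate 2. All 6 lower calls were lost as well with only the groups compared and with the replicate block. Limma-voom did not call CPVL, C15orf48, ENSG00000259342 or B4GALT5. DESeq2 size factors and upper-quartile scaling each ended the B4GALT5 call. Leaving out HORMAD1 replicate 1 alone gave 11 genes higher and 28 lower in edgeR. Leaving out all 3 libraries with the steepest length trend gave 162 higher and 177 lower, which included all 7 genes called with 12 libraries. That fit had 5 residual degrees of freedom, and the libraries left out were chosen from these data. The larger counts therefore do not show further differences between the lines.

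The NF-kB and inflammatory list was lower in the double than in the HORMAD1 line (median log2 fold change -0.35, 16 of 18 members below 0, camera adjusted p = 1.28e-08 with Benjamini-Hochberg adjustment), and this call held with an estimated correlation (adjusted p = 0.0402). No other list call of the 6 comparisons held with an estimated correlation. The adjustment covered the 25 lists of this comparison alone, not the 6 comparisons together. With an estimated correlation, the list's unadjusted camera p was 0.00161. Adjusted over the list alone, 5 of its members passed against 0 over all genes: BIRC3 and TNFAIP3 (edgeR adjusted p = 0.000927 each), PTGS2 (0.00343), IL1A and the chemokine CXCL2 (0.0237 each). Lower by camera were also the epithelial list (-0.18, 24 of 29, 8.77e-08; adjusted p = 0.215 with an estimated correlation), the YAP/TAZ list (-0.26, 18 of 21, 1.69e-05; adjusted p = 0.497 with an estimated correlation) and the luminal list (-0.3, 8 of 11, 0.00212; adjusted p = 0.215 with an estimated correlation). Adjusted over the list alone, edgeR called 6 of the 29 epithelial members (among them CLDN4 at 0.00738, CDH1, OCLN and OVOL1 at 0.0143 and MARVELD2 at 0.0359) and 0 over all genes. In the luminal list it called the aldehyde dehydrogenase ALDH1A3 (-0.45, 0.00536), and in the YAP/TAZ list NUAK2 (0.00949) and CCN1 (-0.72, 0.0223), adjusted over the list alone, against 0 over all genes. Over all genes the edgeR adjusted p was 0.0811 for BIRC3, 0.124 for TNFAIP3, 0.157 for CLDN4, ALDH1A3 and NUAK2, and 0.242 for CDH1. Of lists that camera did not call here, IFI44 (0.52) and MX1 (-0.9) of the interferon list (edgeR adjusted p = 0.0256 each), ANGPTL4 of the hypoxia list (0.72, 0.00408), INHBA of the TGF-beta list (-0.52, 0.043) and HBEGF of the EGFR list (-0.59, 0.0495) passed adjusted over the list alone.

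Immediate early genes (-0.36, 12 of 12 below 0, camera adjusted p = 0.00321; adjusted p = 0.392 with an estimated correlation) and mitosis genes (-0.13, 16 of 19, 0.0104; adjusted p = 0.392 with an estimated correlation) were lower as well. Ribosomal protein genes (0.12, 44 of 46 above 0, camera adjusted p = 1.28e-08; adjusted p = 0.597 with an estimated correlation), mesenchymal genes (0.29, 15 of 23, 0.00435; adjusted p = 0.527 with an estimated correlation) and replication-dependent histone genes (0.19, 8 of 12, 0.0339; adjusted p = 0.215 with an estimated correlation) were higher by camera. In these 5 lists 0 members passed over all genes or adjusted over the list alone. The fibroblast marker FAP was at 22.4 to 22.5 against 19.3 to 20.4 CPM (edgeR adjusted p = 0.705). DCN was at 0.532, 0.526 and 1.41 against 0.27, 0 and 0 CPM. LUM was at 0.444, 0.438 and 1.31 against 0.337, 0 and 0 CPM. MFAP5 was at 0.355 to 1.23 against 0.674 to 1.4 CPM. The mean of the NF-kB list was -0.14 ± 0.1 in the double line and 0.25 ± 0.19 in the HORMAD1 line, and that of the epithelial list -0.12 ± 0.06 and 0.07 ± 0.04. In both, 3 of 3 double libraries lay below all HORMAD1 libraries (SD, n = 3; exact two-sided permutation p = 0.1, the smallest possible).

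The NF-kB, epithelial, YAP/TAZ and luminal calls against the HORMAD1 line held without any 1 of the 12 libraries (camera adjusted p at most 9.6e-05, 0.000513, 0.00539 and 0.0467). Without HORMAD1 replicate 1 the immediate early (0.356), mitosis (0.132), histone (0.198) and ribosomal protein (0.0545) calls were lost, and the first 3 also without the 3 libraries with the steepest length trend (0.378, 0.218 and 0.306). The mesenchymal call was lost without HORMAD1 replicate 2 (0.126), HORMAD1 replicate 3 (0.0768) or double replicate 3 (0.172), the mitosis call without double replicate 2 (0.0768), and the histone call without HORMAD1 replicate 2 (0.0903), double replicate 2 (0.0632), after correction for length and GC content (0.0946) and in limma-voom (0.0703).

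**Figure D3:**
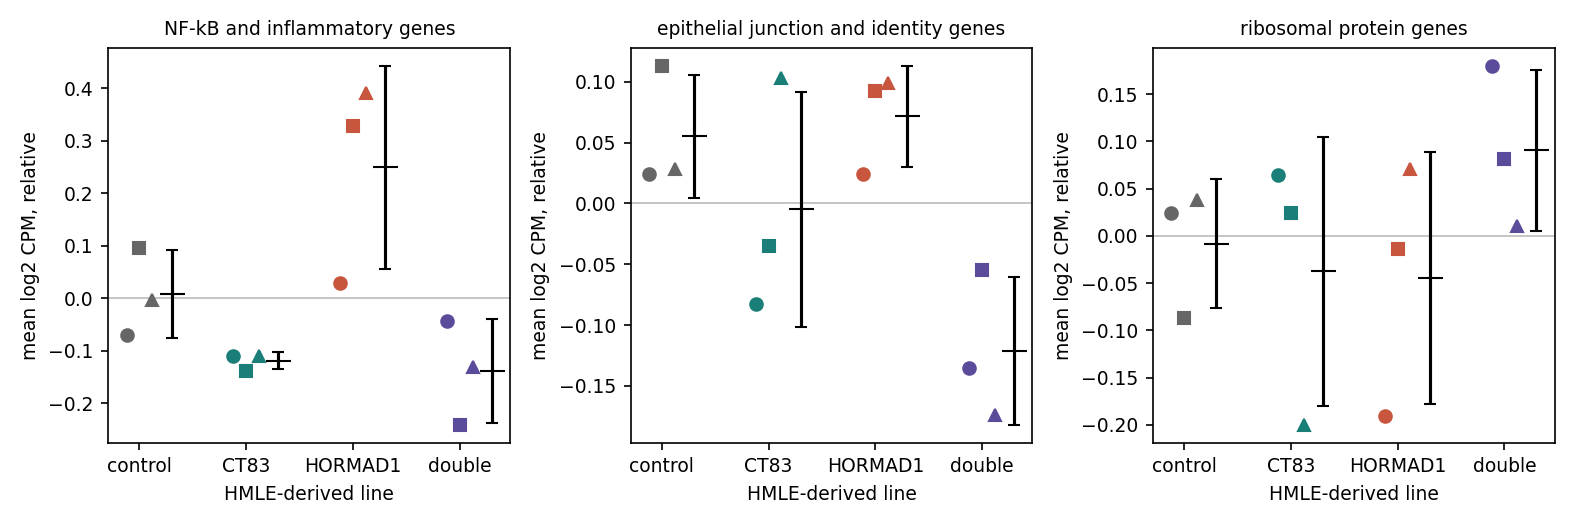
Mean log2 CPM over the members of 3 gene lists, relative to the 12-library mean, in each library by HMLE-derived line; circles, squares and triangles are replicates 1, 2 and 3, and the bars are mean ± SD (n = 3). All 3 double libraries lay below all 3 HORMAD1 libraries in the NF-kB and epithelial lists, while the ribosomal protein values of the lines overlapped.

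The interaction asked whether the double line departed from the sum of the 2 single effects on the log2 scale, while the double line held 19.5% of the CT83 transcript of the CT83 line. In the mesenchymal list the departure was positive by camera (adjusted p = 1.26e-06; adjusted p = 0.3 with an estimated correlation), with SNAI2 at 0.53 (SE 0.18), VIM at 0.59 (SE 0.2) and the fibrillin FBN1 at 2.96 (SE 0.92). FBN1 stood highest in double replicate 3 (8.96 CPM) and control replicate 3 (7.84 CPM), and the fibroblast markers DCN (1.41 CPM) and LUM (1.31 CPM) were also highest in double replicate 3. BIRC3 (-0.6, SE 0.16), TNFAIP3 (-0.43, SE 0.16) and IL1A (-0.39, SE 0.15) had negative values, and the cytokine IL6 of the same list a positive one (1.12, SE 0.41). Of 18 interferon-stimulated genes, 14 had values above 0, such as IFI44 (0.49, SE 0.2) and OASL (0.68, SE 0.33), and 4 below 0. The list was positive by camera (adjusted p = 0.00317; adjusted p = 0.3 with an estimated correlation).

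EdgeR called 0 genes for the interaction in either direction, with an adjusted p of 0.841 for the members named here. An unadjusted p under 0.05 was reached by 703 genes (4.5%), DESeq2 called 2 genes higher and 1 lower, and limma-voom 0. Adjusted over the list alone, edgeR called BIRC3 (0.0424) and the growth factor HBEGF (-0.85, 0.0456), against 0 over all genes. On leaving out the 3 libraries with the steepest length trend, edgeR called 15 genes higher and 7 lower.

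By camera with Benjamini-Hochberg adjustment, 6 lists departed from the sum. Positive were ribosomal protein genes (median 0.16, 45 of 46 above 0, adjusted p = 1.93e-08; adjusted p = 0.696 with an estimated correlation), mesenchymal genes (0.38, 18 of 23, 1.26e-06; adjusted p = 0.3 with an estimated correlation), interferon-stimulated genes (0.2, 14 of 18, 0.00317; adjusted p = 0.3 with an estimated correlation) and stress response genes (0.19, 15 of 19, 0.0158; adjusted p = 0.696 with an estimated correlation). Negative by camera were NF-kB genes (-0.39, 15 of 18 below 0, adjusted p = 0.00317; adjusted p = 0.3 with an estimated correlation) and epithelial genes (-0.12, 24 of 29, 0.0329; adjusted p = 0.696 with an estimated correlation). The NF-kB call was lost without HORMAD1 replicate 3 (camera adjusted p = 0.114), and the stress call without HORMAD1 replicate 1 (0.452) or double replicate 2 (0.154). The epithelial call was lost without CT83 replicate 3 (0.251), HORMAD1 replicate 2 (0.14), HORMAD1 replicate 3 (0.192), double replicate 3 (0.191) or control replicate 1 (0.0877), and after correction for length and GC content (0.147). Without the 3 libraries with the steepest length trend, the interferon (camera adjusted p = 0.0659), ribosomal protein (0.082) and stress (0.319) calls were lost.

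Each single line called its own transgene alone, so a shared gene was not possible and the overlap of 0 says nothing of a shared response. Their log2 fold changes against the same controls had a covariance of 0.00433 across 12278 genes, against 0.0185 in 20 simulations of unchanged groups set against shared controls, a difference of -0.0141. The correlation was 0.21 against 0.5 simulated, and 58.3% of genes had the same sign against 66.5%. Genes are not independent replicates. The simulated libraries were drawn without a trend on transcript length, whereas control replicate 2, CT83 replicate 3 and HORMAD1 replicate 1 rose steeply with it. The difference therefore does not show opposite responses of the single lines.

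Libraries of the same line differed along transcript length and GC content. Control replicate 2, CT83 replicate 3 and HORMAD1 replicate 1 had slopes of 0.058, 0.112 and 0.108 log2 units per SD of log length. Double replicate 1 had -0.097. Their slopes per SD of GC content, from the same fits, were 0.056, 0.116, 0.079 and -0.103. These fits explained 15%, 22.8%, 16.5% and 23.8% of the variance of the libraries' log2 ratios to the mean library. Length and GC slopes had the same sign in each of the 12 libraries. What went with a library's length slope could therefore also go with its GC slope. The proliferation marker MKI67, with a longest transcript of 12678 bases, was at 19.5 to 136 CPM within the control line, 31.8 to 242 in the CT83 line, 13 to 202 in the HORMAD1 line and 17.5 to 34 in the double line. Its log2 fold changes against control were 1.08, 0.4 and -1.17 in the CT83, HORMAD1 and double lines, with SE of 1.22, 1.22 and 1.28, and differences of this size were not detectable. The geometric mean of 18 other mitosis genes stayed between 122 and 156 CPM in all 12 libraries. Other splits of the same libraries into groups of 3 called a median of 4 to 6 lists by camera with the preset correlation, against the real 4 to 9.

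**Figure D4:**
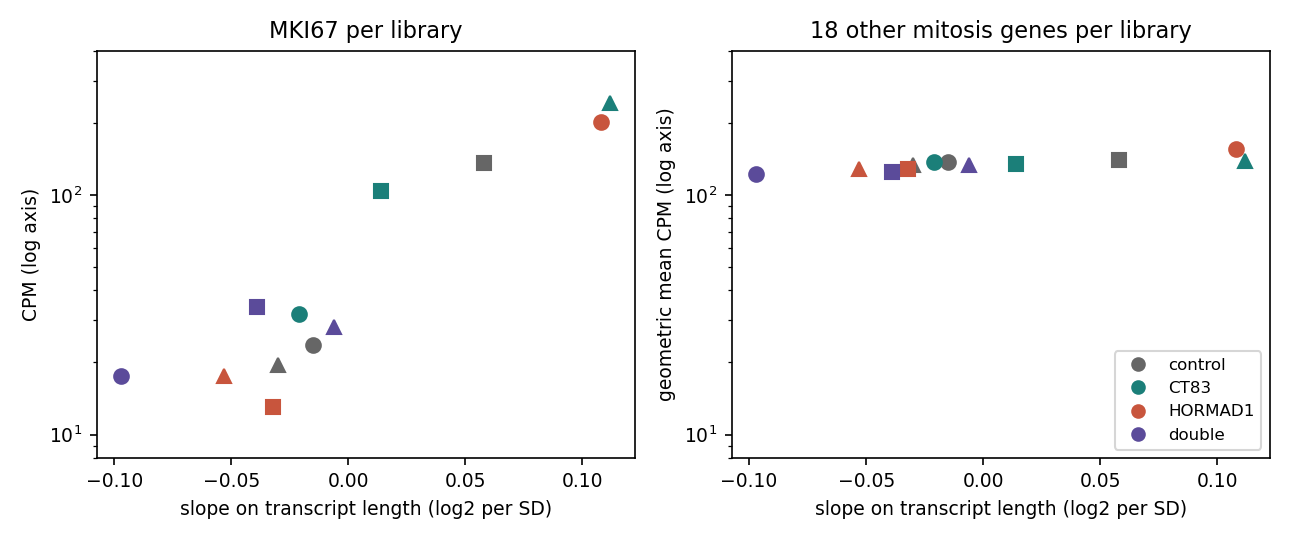
CPM of MKI67 (left) and geometric mean CPM of 18 other mitosis genes (right), both on a log axis, against each library's slope on transcript length (log2 per SD) for the 12 libraries; colours are lines, and circles, squares and triangles are replicates 1, 2 and 3. MKI67 spanned 13 to 242 CPM while the other mitosis genes spanned 122 to 156 CPM.

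In no comparison were 11 further lists called. Their lowest camera adjusted p was 0.0581 for basal and myoepithelial and for extracellular protease genes, 0.0617 for DNA replication, 0.0956 for mitochondrially encoded mRNAs, 0.144 for Wnt targets, 0.179 for EGFR and MAPK response, 0.212 for p53 targets, 0.237 for cholesterol synthesis, 0.302 for TGF-beta response, 0.475 for meiosis and 0.723 for homologous recombination genes. Of the markers of other cell types, 2 of 10 fibroblast, 3 of 10 immune and 0 of 10 endothelial genes were expressed enough to test, too few for a list test, as were 0 of 18 X-linked cancer/testis genes. PTPRC and PECAM1, markers of leukocytes and endothelium, averaged 0.00839 and 0.366 CPM.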

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

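Except for the comparison of the NF-kB list with matched random lists, the tests of explanations here and the counts of other splits were chosen after the results they bear on were seen.

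In 6 gene lists the effect of HORMAD1 differed between cells with and without CT83, by camera's test of the interaction with Benjamini-Hochberg adjustment. The adjusted p was 1.93e-08 for ribosomal protein genes, 1.26e-06 for mesenchymal genes, 0.00317 for both interferon-stimulated and NF-kB genes, 0.0158 for unfolded protein and integrated stress response genes and 0.0329 for epithelial genes. None of these calls held with an estimated correlation, where the adjusted p was 0.3 or 0.696. The double line held 19.5% of the CT83 transcript of the CT83 line, so a departure from the sum of the 2 single effects could also come from this lower level, which was not tested. Of 100 splits of the 12 samples, 48 called as many lists as the real 6, with up to 13 in another split, and chance cannot be excluded. For genes, all 100 splits called at least the real 0, as any split must, so this count decides nothing; 703 genes reached an unadjusted p under 0.05, DESeq2 called 2 higher and 1 lower and limma-voom 0. The split with the most edgeR calls had 1479 genes. It was 1 of 5 splits that put control replicate 2, CT83 replicate 3 and HORMAD1 replicate 1 in 1 group. The others of this kind called 393, 3, 0 and 0 genes, and splits that parted these libraries called at most 5. High counts thus arose only with these libraries together, but not in each such split. A structure of the samples that crosses the lines stays possible.

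NF-kB and inflammatory genes were lower in the double than in the HORMAD1 line. The list was not called in the double line against control (camera adjusted p = 0.0636) or against the CT83 line (0.846). Its mean was 0.25 in the HORMAD1 line, 0.01 in control, -0.12 in the CT83 line and -0.14 in the double line. A trend on transcript length and GC content as the whole cause of the difference from the HORMAD1 line is argued against. After the correction for it the list stayed called (camera adjusted p = 2.6e-10), and the difference of means was -0.42, against -0.39 before. Within lines, the list's relation to the length slope was r = -0.53 before (permutation p = 0.0769, rho = -0.57, r = -0.24 without the 2 farthest libraries). It was r = -0.3 after, so a part of the trend may remain. A single library is argued against as well, since the highest camera adjusted p with each library left out was 9.6e-05. Both camera values are with the preset correlation. The expression level and length of the members are argued against by 10000 random lists matched on both, of which 0 had a median as low as -0.35, although such lists do not share the members' estimated correlation of 0.062. A difference between the lines unrelated to the transgenes cannot be told apart from an effect of the transgenes, because each combination had 1 line (exact two-sided permutation p of the list's mean = 0.1, the smallest possible). An effect of the transgenes stays open, as untested.

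By camera with the preset correlation, ribosomal protein genes were higher in the double line than in the other 3 lines, but not with an estimated correlation (adjusted p = 0.689, 0.814 and 0.597 against the control, CT83 and HORMAD1 lines). Against control the list stayed called after the length and GC correction (camera adjusted p = 0.000389), with a difference of mean log2 CPM of 0.07 (exact two-sided permutation p = 0.3). Within lines, however, the list still followed the slope on transcript length after the correction (r = -0.94). A property of the libraries that goes with this slope therefore cannot be told apart from a difference between lines, and an effect of the transgenes stays open, as untested.

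MKI67 and other long transcripts differed between libraries of 1 line. MKI67 had a within-line SD of 1.54 on the log2 scale against a median of 0.13 over 6160 genes, and 18 of the 20 genes with the largest SD were longer than the median of 3481 bases. A smooth trend on length and GC content as the whole cause is argued against for MKI67, whose SD was 1.35 after its removal. It is argued against as well for the first within-line axis, which held 38.9% of the variance before and 32.9% of the remaining variance after. These shares are of different totals. The common coefficient of variation within lines fell from 13.9% to 11.8%, so the shares may understate what the correction removed. The trend stays open for PLEC (SD 1.21 before and 0.31 after), TNRC18 (1.05 and 0.28), COL7A1 (1.01 and 0.42) and HCFC1 (0.77 and 0.34). Proliferation as the whole cause, the one biological explanation tested, is argued against for the mitosis genes as a group, since the other 18 moved by 0.045 log2 units per log2 unit of MKI67 (r = 0.76, permutation p = 0.00307; rho = 0.67, p = 0.0202; r = 0.53 without the 2 farthest libraries), but not for each of them, since their SD had a median of 0.1 and a highest value of 0.96. Sequencing depth stays open (r = 0.2, permutation p = 0.537; rho = -0.13, p = 0.699; r = -0.48 without the 2 farthest of 12 libraries).

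Between pairs of lines, 3 samples against 3 make 10 splits, too few for a share under 0.05. For genes, the real split called 1, 1, 4, 1 and 7 in the CT83, HORMAD1 and double lines against control and in the double line against the CT83 and HORMAD1 lines, and the highest other split 0 in each, so that 1 of 10 splits reached the real count. These counts hold the transgenes, which no other split can separate. Without them the real counts were 0, 0, 2, 0 and 6, and where the real count was 0 every split reached it, so that the count of splits decides nothing there. For lists, the real 7, 5, 5, 4 and 9 were reached by 2, 5, 4, 9 and 3 of 10 splits, and the highest other splits called 11, 6, 9, 10 and 10.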

How the results depend on the processing

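The correction for transcript length and GC content and the removal of the 3 libraries with the steepest length trend were added after the data were seen; the other alternatives were planned. Among gene lists in the 6 comparisons, 3082 tests stayed on their side of the threshold, 185 of these with another sign and past the threshold in neither setting. A further 109 no longer passed it, 2 turned direction with a call, and the others passed it in addition. Among named genes 4482 values stayed (49 with another sign, past the threshold in neither setting), 71 no longer passed, 0 turned with a call and 59 passed in addition. The 2 lists that turned with a call were luminal genes, higher in the HORMAD1 line than in control without the 3 libraries (camera adjusted p = 0.0407), and mitochondrially encoded mRNAs, higher in the double than in the HORMAD1 line without double replicate 3 (0.0428). Over the 12 libraries left out in turn, the latter ranged from 0.00483, called lower without double replicate 2, to 0.849, against 0.756 with all 12. A median SE of 0.13 on the log2 scale, with 9898845 to 14159740 counts per library, limits what 3 samples per line could detect. Scaling by ERCC spike-ins was not run, since the files held no such entries. The cause of these changes was not tested, except that a stricter threshold leaves fewer calls by construction.

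Counts that moved by over 1.5 times are given as genes higher, then lower, by edgeR unless another tool is named. Without a low-count filter, the CT83 line against control had 0 higher, the double line against control 10 lower, against the CT83 line 0 higher, against the HORMAD1 line 53 and 46, and the interaction 1 and 1. By DESeq2 the HORMAD1 line against control had 2 higher, the double line against the CT83 line 2 and 1, against the HORMAD1 line 28 and 29, and the interaction 2 and 1. By limma-voom the double line had 0 lower against control, 1 lower against the CT83 line and 2 lower against the HORMAD1 line. With only the groups compared, the CT83 and HORMAD1 lines against control had 0 higher, and the double line 4 lower against control and 0 lower against the HORMAD1 line. After the length and GC correction, the CT83 line against control had 0 higher, the double line 1 and 1 against control and 4 higher against the HORMAD1 line. With library size alone the double line against control had 1 lower, and with upper-quartile scaling 3 higher against the HORMAD1 line. At an adjusted p under 0.01, the CT83 line against control had 0 higher, the double line 1 and 0 against control and 0 and 0 against the HORMAD1 line. Without the 3 libraries, the CT83 line against control had 40 and 79, the HORMAD1 line 6 higher, the double line 10 lower against control, 42 and 31 against the CT83 line, 162 and 177 against the HORMAD1 line, and the interaction 15 and 7.

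With the replicate block, the double line had 0 genes lower against control, 1 lower against the CT83 line and 0 lower against the HORMAD1 line. Of 18 pairs of samples with the same number in different lines, 6 had a correlation of deviations above 0.1 (-0.35 to 0.35, mean -0.04 against 0.02 for other pairs), and 4 of 12 libraries correlated best with their own number, so the numbers were not taken to pair the samples.

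With an estimated correlation, 0 lists were called by camera in every comparison but the double against the HORMAD1 line, with 1. Lists called were 8 in the HORMAD1 line by limma-voom, 8 in the double line against control after the length and GC correction, 2 against the CT83 line with upper-quartile scaling, 8 without a filter and 2 without the 3 libraries, and 10 for the interaction without a filter.

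Leaving out each library in turn gave 0 to 1 genes higher and 0 to 0 lower in the CT83 line, 1 to 2 and 0 to 0 in the HORMAD1 line, and 1 to 2 and 0 to 4 in the double line against control (4 without HORMAD1 replicate 1). The double line had 1 to 1 and 0 to 1 against the CT83 line (1 lower without CT83 replicate 3), 0 to 11 and 0 to 28 against the HORMAD1 line (11 and 28 without HORMAD1 replicate 1), and the interaction 0 to 0 and 0 to 0. Lists called ranged from 2 to 9, 3 to 7, 5 to 8, 1 to 6, 6 to 11 and 5 to 9 in the same order, and genes shared by the single lines from 0 to 0.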

Other observations

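The cells expressed a mixed keratin profile in all lines, with mean levels of 3850 CPM for KRT7, 2920 for KRT5, 2160 for KRT8, 2030 for KRT6A and 1640 for KRT17, while the luminal keratin KRT19 was at 0.64 CPM. The receptors ESR1, PGR and KIT were near or at the floor, with ESR1 at 0.827 CPM and no count of PGR or KIT in any library. Of 18 X-linked cancer/testis genes, 17 had no count in any library, those of the CT83 line included, and PAGE2 had 1 count in all. Among meiosis genes, SYCE2 (9.53 CPM) and SYCP3 (5.34 CPM), components of the synaptonemal complex, were present in all lines. CSF1R, the receptor of a macrophage growth factor, was at 146 CPM (119 to 164 over the 12 libraries), while the leukocyte marker PTPRC was at 0.00839 and CD14 at 6.03 CPM.

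Single libraries stood apart in matrix genes. COL1A2 was at 18.9 CPM in control replicate 3 and at most 0.432 CPM elsewhere, and COL3A1 at 6.57 against at most 0.956 CPM, while the fibroblast markers DCN and LUM were at 0.253 and 0.0843 CPM in that library. Double replicate 3 had the highest COL1A1 (60.5 CPM), FBN1 (8.96 CPM), DCN (1.41 CPM) and LUM (1.31 CPM).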
